A study of Mus musculus with 4 samples.

How the data were processed

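RNA was measured in 4 libraries of mouse trophoblast stem cells, the self-renewing cells derived from the trophectoderm lineage that forms the placenta. The cells carried a lentiviral short hairpin RNA, either a scrambled sequence (2 libraries) or one directed at Tead4 (2 libraries). Per the labels' protocols, they were kept in stem conditions with 20% serum, FGF4 and heparin, selected with puromycin at 1.5 µg/ml, and passaged before harvest. RNA with an integrity value above 7.0 went into RNA-seq libraries made with an Illumina TruSeq kit. The labels number the libraries of each group as sets 1 and 2 and do not say what a set is, so p-values measure the spread between these libraries, which may be technical.

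The values are FPKM, fragment numbers scaled by transcript length and library size, as the authors deposited them in 1 table with a column per library. Per the submitters' processing notes, STAR, Cufflinks and Cuffdiff were used with the GRCm38 (mm10) mouse build; their versions and settings are not given in the sources used here. The table held 37322 rows, of which 14376 were 0 in every library. In 693 rows several overlapping genes shared a value, and such a row is described here by all the names it carries or by the gene of interest with a remark. Columns were matched to libraries by name, and all 4 value columns were used. Gene positions are those of the table, converted to 1-based coordinates, and equal those of the reference annotation of the same build for Tead4.

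The number of fragments per library is unknown, because FPKM removes it. Low values move in steps of 1 fragment, and these steps were compared between libraries for rows between 0 and 0.5 FPKM in both. In set 2 the commonest ratio was sharp: 13.7% of 3427 rows had a value 1.39 times higher with Tead4 shRNA than with scramble shRNA, as if 1 fragment weighed that much more there. For the set 1 libraries the commonest ratio was 0.979, shared by 1.41% of rows, so no depth could be read from it. The FPKM summed to 541258 and 543897 in the scramble libraries and to 619790 and 622911 in the Tead4 shRNA libraries.

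FPKM are not counts, so no count model was used. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, the group as the only term and all 4 libraries in the fit. Fold changes are on that scale, which understates the change of low genes. Rows with a mean of at least 1 FPKM over the 4 libraries were tested. Small RNA genes and mitochondrial tRNA and rRNA were left out because length-scaled values of very short genes are unstable; this removed 51 rows that passed the level filter and left 12772 rows. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all rows tested, with a threshold of 0.05. With 2 libraries against 2 there are 3 splits, so an exact permutation test cannot go below p = 0.333, and the test rests on a spread shared across genes.

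Before the data were examined, 23 gene lists, the rule for the genes named, the tests and most alternatives were fixed. The lists were tested with camera, a competitive test of a list against all other genes, with a preset inter-gene correlation of 0.01 and again with a correlation estimated from the data, both adjusted over the 23 lists. The second form has only the 2 residual degrees of freedom of the fit. Named genes are Tead4, the 12 largest positive and 12 largest negative fold changes past the threshold with non-overlapping groups (predicted gene models passed over), 3 members of each list with the largest limma statistic, and 11 trophoblast and TEAD pathway genes fixed by name. Other list members are named only to show what a list's count is made of. Y-linked genes, Xist, Hox genes, and the cadherins, keratins, repressors, cytokines and other single genes of the closing section were chosen after their values were seen.

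The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalisation, rescaling of each library to the same sum (TPM-like), and no intensity trend. Others were the set number as a block, small RNA genes kept, and each library left out in turn. In the last, the lone library of a group is assumed to vary like the other group. A call gained without a scramble library can therefore rest on the difference between the scramble libraries. Leaving out further small RNA names and counting only genes with a log2 fold change of at least 1 in size were added after the data were seen. The tests were tried on simulated data, in 20 simulations of this comparison over 12772 genes with the fitted spread of each gene and 200 genes changed. Of these, 45.2% of genes changed by 1 on the log2 scale and 99.9% of those changed by 3 were called in the right direction. The changed genes were drawn from rows with a higher minimum level than the filter, so recovery of the lowest genes was not tried. They were also far fewer than the genes called in the data. Of the simulated calls, 8.63% were genes that had not been changed, above the nominal threshold. Lists of 20 shifted genes had an unadjusted camera p under the threshold in 20 of the 20 simulations, and unchanged lists in 0. Genes were simulated independently of each other, so this does not show how camera with the preset correlation treats correlated genes. In the data the estimated correlation reached 0.923, among the mitosis genes.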

Results

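Transcripts of mouse trophoblast stem cells were compared between 2 libraries with scramble shRNA and 2 with an shRNA against Tead4, a DNA-binding partner of the YAP and TAZ coactivators that is needed for the trophectoderm lineage. The comparison asks which transcripts differ when Tead4 is knocked down under stem culture conditions. Values are the authors' FPKM; total fragments per library are unknown, and Spearman correlations across the tested genes, which are not independent replicates, were 0.957 within the scramble pair, 0.985 within the Tead4 shRNA pair and 0.794 to 0.825 between groups.

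Tead4 (protein coding, minus strand, GRCm38 chromosome 6, 128224288 to 128300823) stood at 45.3 and 29.8 FPKM in the scramble libraries and at 10.6 and 16.0 FPKM in the Tead4 shRNA libraries. It was 2.68 times lower on the log2(FPKM + 1) scale (log2 fold change −1.42, SE 0.296, limma adjusted p = 0.0164). Tead4 shRNA was accompanied by changes in 31.1% of the 12772 genes tested: 2239 were higher and 1731 lower. Y-linked genes, described below, were higher with Tead4 shRNA and nearly absent from the scramble libraries. These counts therefore cannot separate an effect of the shRNA from a difference in the cells present. The larger changes were mostly increases, with 371 genes higher and 6 lower by at least 3 on the log2 scale. Among the higher genes, 779 had a scramble mean under 1 FPKM; among the lower genes, 232 had a Tead4 shRNA mean under 1 FPKM. The groups did not overlap for any of the 3970 called genes, nor for 69.3% of all genes tested, where chance gives 33.3%. The split depended on scaling, 56.4% of calls being higher as deposited, 43.7% after quantile normalisation and 41.5% after TPM-like rescaling. Without Tead4 shRNA library 1, 845 genes were higher and 81 lower, and without library 2, 793 and 84; Tead4 then had adjusted p = 0.191 and 0.0950, within a range of 0.000162 to 0.191 over all alternatives.

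The largest increase was that of Spp1, which encodes osteopontin. It rose from 5.02 ± 4.91 to 7232 ± 302 FPKM (SD, n = 2; log2 fold change 10.52, SE 0.577, limma adjusted p = 0.000128). Mgp, an inhibitor of matrix calcification, went from 0.667 to 2005 FPKM, and Vim, the intermediate filament of mesenchymal cells, from 1.16 to 1555 FPKM. S100a4, a calcium-binding protein, reached 1749 FPKM from 1.49, and the metalloproteinase inhibitor Timp1 1404 FPKM from 2.66. The proteoglycan Bgn, the matricellular protein Thbs1, Serpinf1, Igfbp7, Tm4sf1, Cpe and the monocyte chemoattractant Ccl2 completed the 12 largest increases, with log2 fold changes of 7.59 to 9.01 and adjusted p of 4.65e-05 in limma. None of these 12 calls was lost under an alternative, but no alternative bears on RNA from other cells. The fibroblast markers and Y-linked genes described below were higher in the same libraries.

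A list of fibroblast markers had been fixed for cells that could accompany trophoblast cultures. All 20 rose, 20 when adjusted over the list alone. Their median log2 fold change was 4.37 (camera adjusted p = 1.25e-16; adjusted p = 0.526 with an estimated correlation). Col1a2, a chain of type I collagen, stood at 0.0896 ± 0.0442 and 115 ± 13.5 FPKM (SD, n = 2), smooth muscle actin Acta2 at 0.0670 and 94.8 FPKM, and the collagen cross-linking enzyme Lox at 0.176 and 82.3 FPKM. Thy1 was the most abundant marker with Tead4 shRNA, at 159 FPKM. In the scramble libraries 7 of the 20 markers averaged 1 FPKM or more, and Lum was listed at 0 in both. Chosen after values were seen, the 4 broadly expressed Y-linked genes were at most 0.0506 FPKM in a scramble library. With Tead4 shRNA, Eif2s3y (Y chromosome, 1010543 to 1028847) averaged 25.7 ± 1.01 FPKM, Ddx3y 13.3 ± 1.55, Uty 4.35 ± 0.397 and Kdm5d 2.41 ± 0.178 FPKM (SD, n = 2). Xist, the RNA of the inactive X chromosome, was present in both groups, at 126 and 104 FPKM in the scramble and 60.8 and 75.3 FPKM in the Tead4 shRNA libraries (log2 fold change −0.75, limma adjusted p = 0.0434). Its antisense partner Tsix, given the same span in the table, had its own row at 0.0802 FPKM or less, and the sources used here do not say whether strand was used. Without Tead4 shRNA library 1 the marker median was 4.52, over 19 rows tested, and without library 2 it was 4.27, over 20. Not every marker kept its call in these runs, and Xist, at −0.59 and −0.90, lost its call in both. With no filter on low values Xist had limma adjusted p = 0.0710.

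**Figure D1:**
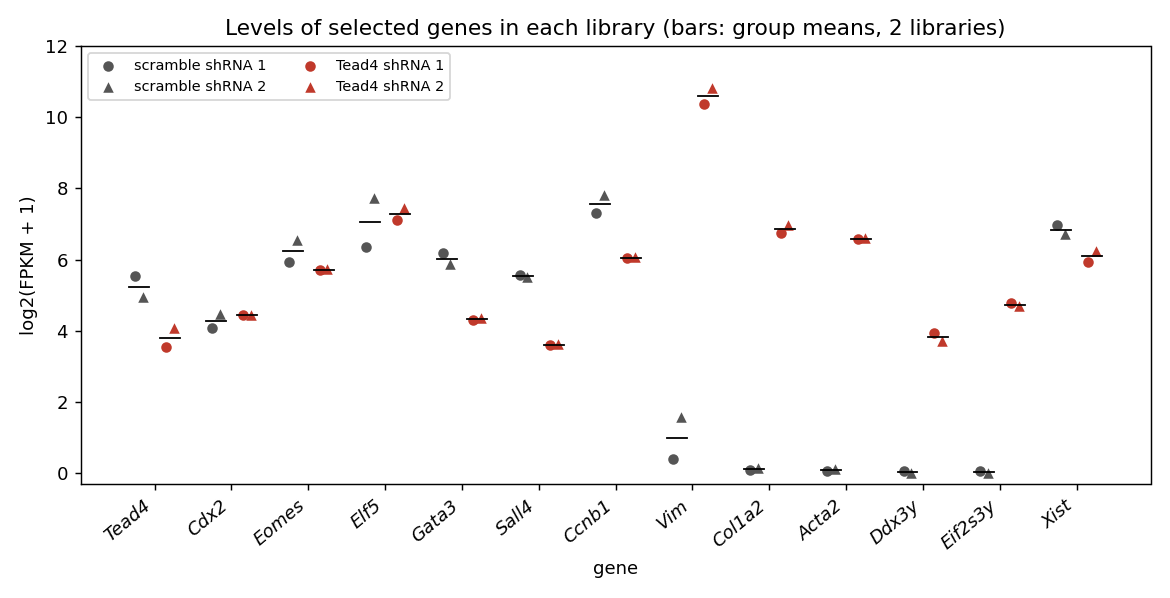
Levels of 13 genes in each library as log2(FPKM + 1), with grey symbols for scramble shRNA, red for Tead4 shRNA, circles for library 1, triangles for library 2 and bars for group means of 2 libraries. Col1a2, Acta2, Ddx3y and Eif2s3y are near 0 with scramble shRNA and well above it with Tead4 shRNA, Vim averages 1.16 FPKM with scramble shRNA and 1555 FPKM with Tead4 shRNA, while Cdx2 and Elf5 overlap between groups and Xist is present in all libraries.

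The largest decreases were smaller in size than the largest increases. Inpp5d, a phosphatase of phosphoinositide signalling, fell from 28.3 ± 5.41 to 0.790 ± 0.224 FPKM (SD, n = 2; log2 fold change −4.03, SE 0.230, limma adjusted p = 0.000137). The membrane carbonic anhydrase Car4 went from 198 to 9.76 FPKM, the gelatinase Mmp9 from 83.7 to 3.94 FPKM, the gluconeogenic enzyme Fbp2 from 70.2 to 3.79 FPKM and the kininogen Kng2 from 26.7 to 0.940 FPKM. The amino acid transporter Slc38a4, the water and glycerol channel Aqp3, the chemerin receptor Cmklr1, Laptm5, Sept4 (in a row shared with Gm11492), Padi3 and the serine protease Prss42 had log2 fold changes between −3.22 and −2.84. The scramble libraries themselves differed for some of them, Car4 at 309 and 86.8 FPKM and Mmp9 at 132 and 35.4 FPKM. Without a Tead4 shRNA library 5 of these 12 calls were lost: Car4 (highest adjusted p 0.0675 in limma over all alternatives), Mmp9 (0.0825), Slc38a4 (0.0661), Aqp3 (0.0923) and Cmklr1 (0.0531).

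Genes of the trophoblast stem cell state did not pass as a group, in libraries where all 20 fibroblast markers and the Y-linked genes were higher. Of 19 tested, 3 fell, 3 when adjusted over the list alone, and none rose. The median log2 fold change was 0.06 and the mean −0.17, and camera pointed down (adjusted p = 0.419; 0.794 with an estimated correlation). Sall4, a zinc finger regulator of stem cells, fell from 45.4 ± 1.31 to 11.3 ± 0.187 FPKM (log2 fold change −1.92). Gata3, a trophectoderm transcription factor in a row shared with 9230102O04Rik, fell by 1.70 on the log2 scale. Tfap2c, another trophoblast regulator, fell from 161 ± 9.78 to 81.1 ± 4.06 FPKM (−0.98, adjusted p = 0.0109 in limma). The stem cell transcription factors Cdx2 (18.6 ± 3.87 and 20.7 ± 0.101 FPKM, log2 fold change 0.16), Elf5 (0.23), Eomes (−0.51) and Esrrb (−0.52) had limma adjusted p of 0.602, 0.723, 0.172 and 0.201. The scramble pair differed for Elf5, at 81.1 and 212 FPKM, and the counts depended on which was used. Without scramble library 1, 1 stem cell gene rose and 7 fell, among them Eomes (−0.82, limma adjusted p = 0.00373) and Esrrb (−0.86, 0.00505), Elf5 was at −0.45, and camera gave 0.0417, downward, in a range of 0.0417 to 0.794 over the alternatives. Without scramble library 2, 6 rose, among them Elf5 (0.92, limma adjusted p = 0.00288), and 4 fell. Without Tead4 shRNA library 1, Tfap2c and Gata3 had limma adjusted p of 0.169 and 0.0595, and without library 2, 0.134 and 0.0596.

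Lists of the differentiated trophoblast types were mixed. Of 15 giant cell genes, 5 rose and 2 fell, 6 and 3 when adjusted over the list alone (camera adjusted p = 0.0856; 0.794 with an estimated correlation). The rise was led by the proliferins Prl2c2 (4.76 to 270 FPKM) and Prl2c3 (32.5 to 389 FPKM), and by Prl2a1 (5.96 to 26.1 FPKM). Proliferins are prolactin family genes with near-identical copies, among which fragments can be split. Hand1, needed for giant cell formation, fell from 1105 ± 530 to 376 ± 2.90 FPKM. Without scramble library 1, 11 giant cell genes rose and this list passed camera with adjusted p = 0.00807, and after TPM-like rescaling with 0.0454, in a range of 0.00807 to 0.794. Of 7 spongiotrophoblast and glycogen cell genes, 4 rose, among them Aldh1a3 (log2 fold change 1.42) and Prl8a9 (1.29), and the connexin Gjb3 fell (−1.04). Adjusted over the list alone, 4 rose and 3 fell (camera adjusted p = 0.533; 0.794 with an estimated correlation). Of 14 labyrinth syncytiotrophoblast genes, 2 rose, Ror2 (1.51) and the growth factor receptor Met (0.98). Dlx3, a placental homeobox gene, fell from 17.2 ± 0.0598 to 1.79 ± 0.491 FPKM (−2.71). Counts adjusted over the list alone were 2 and 1. That list's median was −0.06 while camera pointed up (adjusted p = 0.993; 0.993 with an estimated correlation). These values come from the libraries in which the 20 fibroblast markers rose. Without Tead4 shRNA library 1, 3 giant cell and 2 spongiotrophoblast genes rose. Without library 2, 2 giant cell genes rose (Prl2a1 had limma adjusted p = 0.0574) and 0 of 5 spongiotrophoblast genes, whose median was then −0.57. In neither did a gene of the 3 lists pass as lower except Dlx3. With no filter on low values 2 spongiotrophoblast genes rose and Hand1 had limma adjusted p = 0.0774. The calls of Ror2 and Met were lost without a Tead4 shRNA library and with no filter on low values (limma adjusted p = 0.0658 and 0.0625), and that of Met after quantile normalisation (0.0645), with highest values of 0.163 and 0.182. Without scramble library 2, 4 giant cell and 4 labyrinth genes passed as lower, and without either scramble library 5 labyrinth genes passed as higher; 3 spongiotrophoblast genes passed as lower without library 1 and 2 without library 2.

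Among imprinted genes of placenta, in the libraries where the 20 fibroblast markers rose, 5 of 20 rose and 6 fell, 5 and 9 when adjusted over the list alone. The non-coding Meg3 (in a row shared with 2 microRNA genes) rose from 3.70 to 280 FPKM and the zinc finger gene Plagl1 from 0.175 to 13.2 FPKM. With no filter on low values 3 rose and 3 fell. The growth factor Igf2 fell from 1996 ± 155 to 724 ± 58.8 FPKM (log2 fold change −1.46, limma adjusted p = 0.00256). The list's median was −0.38, its mean 0.34, and camera pointed down (adjusted p = 0.533; 0.844 with an estimated correlation). Of 5 embryonic stem cell markers tested, Dppa4 fell (−0.93), Klf2 rose (0.74) and Dppa5a was at 7.70, 17.2, 4.80 and 0.432 FPKM without a call. Dppa5a passed as lower after quantile normalisation (limma adjusted p = 0.0429) and without scramble library 1 (0.00381), scramble library 2 (0.0389) or Tead4 shRNA library 1 (0.0407), in a range of 0.00381 to 0.295 over the alternatives. Adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.419; 0.794 with an estimated correlation). Of 9 extraembryonic endoderm markers, 4 rose, with Dab2 from 0.390 to 37.1 FPKM, Pdgfra from 2.11 to 19.6 FPKM and Gata6 from 1.81 to 6.61 FPKM, and 3 fell. The counts were 4 and 3 when adjusted over the list alone (camera adjusted p = 0.516; 0.794 with an estimated correlation). Without Tead4 shRNA library 1 or library 2, 2 imprinted genes were higher and none lower in limma, and Igf2 had adjusted p = 0.0915 and 0.0670. Without scramble library 2, 10 imprinted genes were lower, and 4 embryonic stem cell markers were lower without scramble library 1. Of the endoderm markers 2 rose without Tead4 shRNA library 1 and 1 without library 2, where Pdgfra had limma adjusted p = 0.0661, and none fell; with no filter on low values 1 fell. Without a Tead4 shRNA library the calls of Dppa4 (limma adjusted p up to 0.331), Klf2 (0.351) and Gata6 (0.0975) were lost, as were those of Dppa4 and Klf2 with no filter on low values (0.0860 and 0.0604) and of Klf2 after TPM-like rescaling (0.0857).

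Targets of YAP and TEAD rose where they changed. Of 23 tested, 12 rose and none fell, 15 and 0 when adjusted over the list alone, with a median log2 fold change of 1.04 (camera adjusted p = 0.000255; adjusted p = 0.700 with an estimated correlation). Ctgf, a matricellular growth factor, rose from 2.41 ± 1.47 to 190 ± 3.91 FPKM (SD, n = 2). The receptor kinase Axl rose from 1.01 ± 0.997 to 105 ± 14.0 FPKM and the secreted Ccdc80 from 0.0197 to 23.3 FPKM. The 20 fibroblast markers rose in the same libraries. Cyr61, with 213 and 253 FPKM, did not pass the threshold, but without scramble library 1 it was at 1.57 (limma adjusted p = 6.32e-05) and without library 2 at −0.44 (0.0642). Within the TEAD family and Hippo pathway, 3 of 16 genes rose and 2 fell, 7 and 3 when adjusted over the list alone (camera adjusted p = 0.419; 0.794 with an estimated correlation). Tead3 fell from 53.3 ± 1.78 to 25.5 ± 4.76 FPKM (log2 fold change −1.05, limma adjusted p = 0.0145). Wwtr1, which encodes TAZ, rose from 17.6 ± 3.46 to 45.5 ± 5.83 FPKM (1.33, adjusted p = 0.00829 in limma), as did the cofactor Vgll3 (1.91). Tead1 (−0.14), Tead2 (−0.18) and Yap1 (0.08) had limma adjusted p of 0.674, 0.534 and 0.764. Without either Tead4 shRNA library, 5 YAP and TEAD targets and no Hippo pathway gene passed as higher; Tead3 then had limma adjusted p of 0.205 and 0.106, and Wwtr1 0.151 and 0.101. Without scramble library 1, 18 targets and 8 Hippo pathway genes passed as higher; without library 2, 2 targets passed as lower. With no filter on low values 1 Hippo pathway gene was lower.

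Most immediate early genes and part of the FGF and ERK response genes were higher with Tead4 shRNA. Of 15 immediate early genes 13 rose, 14 when adjusted over the list alone, with a median log2 fold change of 2.61 (camera adjusted p = 1.74e-07; adjusted p = 0.526 with an estimated correlation). Egr3 rose from 0.132 to 27.2 FPKM, the nuclear receptor Nr4a1 from 37.6 ± 2.56 to 355 ± 2.85 FPKM and the transcription factor Klf4 from 11.0 ± 1.50 to 137 ± 7.40 FPKM (SD, n = 2). Of 16 FGF and ERK response genes 8 rose, 9 when adjusted over the list alone, with a median of 1.02 (camera adjusted p = 0.00220; adjusted p = 0.529 with an estimated correlation). Cyclin D1 (Ccnd1) rose from 9.36 ± 0.671 to 200 ± 3.96 FPKM, and the ERK pathway inhibitors Dusp4 from 4.28 to 70.4 FPKM and Spred1 from 2.46 to 31.8 FPKM, again beside the rise of the 20 fibroblast markers. Etv4, Etv5 and Spry4, transcripts commonly read as FGF targets, had log2 fold changes of 0.19, 0.11 and −0.09 without a call. Etv4 passed as lower without scramble library 1 (−0.54, limma adjusted p = 0.0380) and as higher without library 2 (0.93, 0.00262), as did Etv5 without library 2 (0.56, 0.0379). Without either Tead4 shRNA library, 6 immediate early genes and 5 FGF and ERK response genes passed in limma, and without scramble library 1, 2 FGF and ERK response genes were lower.

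Most mitosis genes and part of the DNA replication genes were lower with Tead4 shRNA. Of 24 mitosis genes 21 fell, 24 when adjusted over the list alone, with a median log2 fold change of −1.29, or 2.45 times lower (camera adjusted p = 2.89e-08; adjusted p = 0.753 with an estimated correlation of 0.923 between members). Cyclin B1 (Ccnb1) fell from 190 ± 47.2 to 65.7 ± 1.65 FPKM (SD, n = 2). Cyclin A2 (Ccna2) fell from 78.3 ± 7.43 to 34.5 ± 1.51 FPKM and the spindle midzone protein Prc1 from 81.5 ± 11.7 to 31.3 ± 4.36 FPKM. Of 28 DNA replication genes 11 fell, 13 when adjusted over the list alone, with a median of −0.67 (camera adjusted p = 0.000825; adjusted p = 0.794 with an estimated correlation). Among them were both ribonucleotide reductase subunits, Rrm2 (−1.27) and Rrm1 (−0.80), and the polymerase subunit Pold1 (−1.47). Of 20 p53 target genes 4 rose, 4 when adjusted over the list alone (camera adjusted p = 0.415; 0.794 with an estimated correlation). They included the cell cycle inhibitor Cdkn1a, from 135 ± 26.4 to 422 ± 16.3 FPKM, the death receptor Fas (2.05) and Eda2r (1.07). The fibroblast markers and Y-linked genes were higher in the same libraries. Without either Tead4 shRNA library, 0 of these mitosis, replication and p53 target genes passed limma. Without scramble library 1 the replication median was −0.88 and the p53 target median −0.04. Without scramble library 2 they were −0.37 and 0.38. With no filter on low values 3 replication genes fell, and Pold1 had limma adjusted p = 0.0590; after TPM-like rescaling 1 p53 target fell. Without Tead4 shRNA library 1 or 2, the mitosis median was −1.19 or −1.38 and the replication median −0.62 or −0.74. Camera called the mitosis list with no filter on low values (adjusted p = 7.60e-09) and after TPM-like rescaling (7.29e-07). It called the replication list under the same settings (7.30e-05 and 0.00141). Over all alternatives these p ranged from 2.49e-11 to 0.753 and from 1.50e-05 to 0.794.

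Most mitochondrially encoded mRNAs were higher in the libraries with the fibroblast transcripts, while genes that transcribe and maintain mitochondrial DNA were lower or had no call. Of 10 mitochondrial rows 7 rose, 9 when adjusted over the list alone, with a median log2 fold change of 1.10 (camera adjusted p = 0.00105; adjusted p = 0.753 with an estimated correlation). mt-Cytb rose from 1574 ± 290 to 5664 ± 1077 FPKM (SD, n = 2); mt-Nd5 (1.46) and mt-Nd6 (1.51) also rose but share a locus on opposite strands, and the sources used here do not say whether strand was used. Of 11 genes of mitochondrial DNA transcription and maintenance 2 fell, 1 when adjusted over the list alone (camera adjusted p = 0.0420; adjusted p = 0.700 with an estimated correlation). The polymerase Polg fell from 98.9 ± 33.2 to 33.7 ± 2.17 FPKM and the elongation factor Tefm by 0.81 on the log2 scale (adjusted p = 0.0468 in limma; 0.0852 with no filter on low values, where 1 gene fell). After TPM-like rescaling 5 maintenance genes fell and after quantile normalisation 4. Polg2 was at −0.62 with adjusted p = 0.0526 in limma, and passed as lower after quantile normalisation (0.0278) and TPM-like rescaling (0.0240), with no intensity trend (0.0489) and without scramble library 1 (0.0232) or 2 (0.0295), in a range of 0.0232 to 0.364. Of 75 nuclear-encoded oxidative phosphorylation genes 8 rose, among them Atp5j2 (1.10), Atp5l (0.98) and Ndufa2 (0.80), but after TPM-like rescaling 2 rose and 3 fell, after quantile normalisation 5 and 3, and with no filter on low values 1 rose. Without scramble library 2, 24 rose and 3 fell, without library 1, 9 and 4, and without a Tead4 shRNA library 0 and 0. With p adjusted over the list alone, 0 rose (camera adjusted p = 0.329; 0.844 with an estimated correlation). Of 18 glycolysis genes 6 rose, including Ldha from 289 ± 39.7 to 673 ± 2.38 FPKM and Pgk1 (0.90), and 2 fell, including Hk1 (−1.26). After quantile normalisation 3 rose and 2 fell, and with no filter on low values 3 and 1. Counts adjusted over the list alone were 6 and 2 (camera adjusted p = 0.324; 0.794 with an estimated correlation). Without Tead4 shRNA library 1 none of the mitochondrial rows passed limma and without library 2, 4 did; with no filter on low values 3 did, and mt-Nd6 had limma adjusted p = 0.0657. The camera call of the maintenance list was lost without either (adjusted p = 0.0565 and 0.0601), without scramble library 2 (0.123), after quantile normalisation (0.0787) and with a pseudocount of 0.1 (0.0519), in a range of 0.00948 to 0.700 over all alternatives. Without scramble library 1, 7 maintenance genes fell; without library 2, 10 glycolysis genes rose and 4 fell, and without a Tead4 shRNA library none did.

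Part of the interferon response genes rose in the same libraries as the fibroblast markers. Of 23 tested 13 rose and 10 had no call, 15 higher when adjusted over the list alone, with a median log2 fold change of 1.22 (camera adjusted p = 9.41e-06; adjusted p = 0.700 with an estimated correlation). Ifit3 rose from 0.0658 to 23.3 FPKM, Ifit1 from 0.229 to 15.2 FPKM and Ifit2 from 0.0191 to 3.99 FPKM. Of 20 unfolded protein and amino acid response genes 7 rose, 7 when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.00963; adjusted p = 0.700 with an estimated correlation). They included the cystine transporter Slc7a11 (0.0120 to 8.06 FPKM), the glutathione-degrading Chac1 (1.85 to 14.0 FPKM) and the lipoprotein receptor Vldlr (1.60 to 11.4 FPKM). Of 19 cholesterol synthesis genes 6 rose, with Insig1 from 4.38 to 30.1 FPKM, Sc4mol (1.78) and Cyp51 (1.36), and 1 fell, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0795; 0.700 with an estimated correlation). This list passed camera with no filter on low values (0.0154), a mean of at least 5 FPKM (0.0486) and quantile normalisation (0.0386), in a range of 0.0154 to 0.700; without scramble library 1, 3 of its genes fell. Of 48 cytosolic ribosomal protein genes 3 rose, Rpl30 (1.20, in a row shared with SNORA72), Rps18 (0.86) and Rps27 (0.70), but after quantile normalisation none rose and 2 fell, after TPM-like rescaling 1 rose, and with no filter on low values 0 rose. Without scramble library 2, 17 rose and none fell (camera adjusted p = 0.0201, upward), without library 1, 7 rose and 1 fell, and with no filter on low values camera gave 0.0154, upward, in a range of 0.0154 to 0.794. With p adjusted over the list alone, 0 rose (camera adjusted p = 0.0856; 0.794 with an estimated correlation). Without either Tead4 shRNA library 5 interferon response genes, 2 of the unfolded protein list and 0 ribosomal protein genes passed limma, and 1 or 2 of the cholesterol genes. Without scramble library 1, 12 genes of the unfolded protein list rose and 1 fell, and without scramble library 2, 2 fell and that list had camera adjusted p = 0.0652, in a range of 0.000629 to 0.700.

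With the preset correlation 10 of the 23 lists passed camera, 7 upward and 3 downward. With a correlation estimated from the data 0 passed, the smallest adjusted p was 0.526, and 2 lists, the fibroblast markers and the immediate early genes, had an unadjusted p under 0.05.

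**Figure D2:**
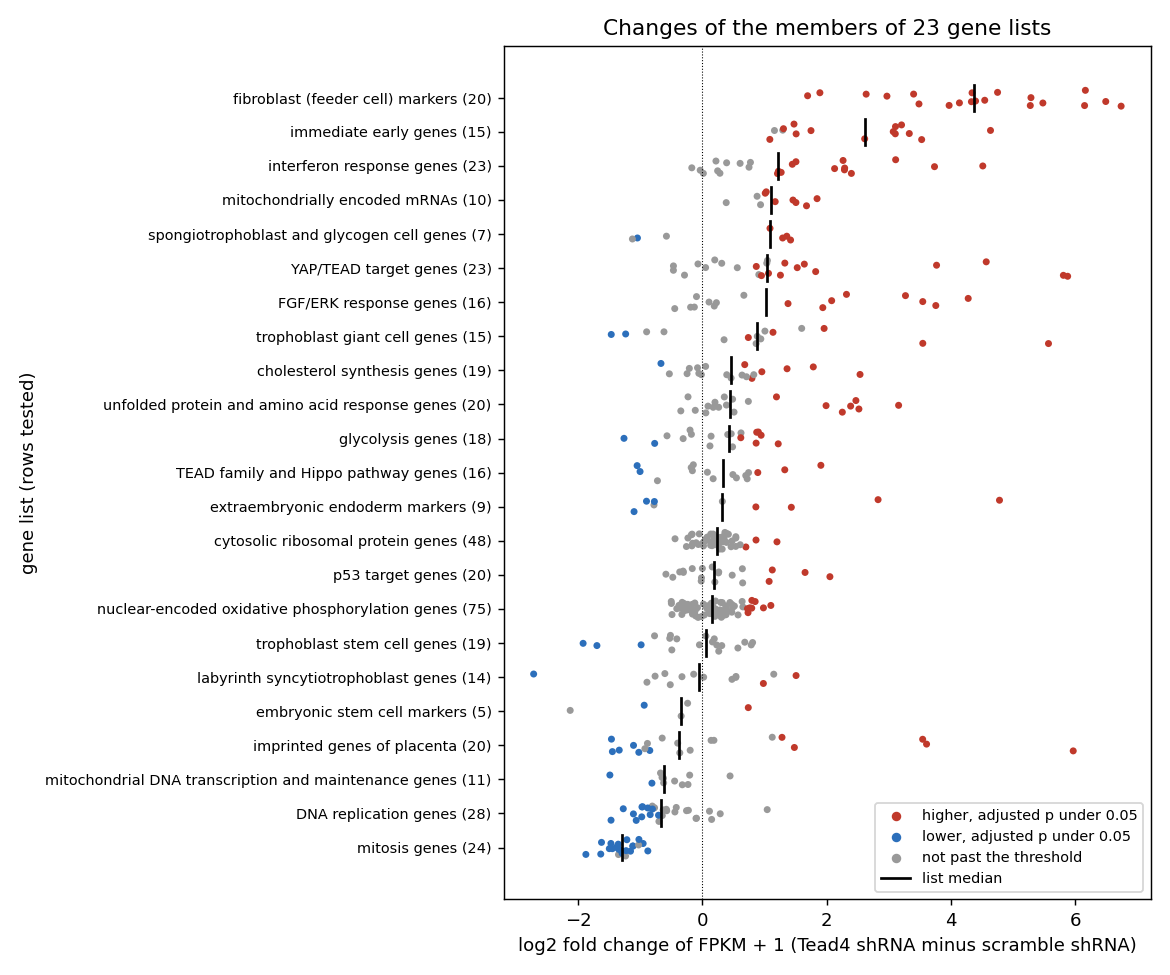
Log2 fold changes of FPKM + 1 (Tead4 shRNA minus scramble shRNA, horizontal axis) of each tested member of the 23 gene lists (rows), red for higher and blue for lower past the adjusted p threshold, grey for no call, and a bar at the list median. Fibroblast markers are all to the right with a median of 4.37, mitosis genes all to the left with a median of −1.29, and trophoblast stem cell genes lie around 0.06.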

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

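Leaving out further small RNA names and counting only genes with a log2 fold change of at least 1 in size were chosen after the data were seen; the other alternatives were fixed before. Over the 4 runs that leave out 1 library, higher genes numbered 793 to 3429, and lower genes 81 to 3060. Tead4's log2 fold change was −1.72 to −1.13, and lists past the threshold numbered 9 to 12. Low counts came without a Tead4 shRNA library, when the spread rests on the less alike scramble pair. High counts came without a scramble library, when it rests on the Tead4 shRNA pair. The difference between the scramble libraries is then left out of the spread. Calls gained only in those runs can reflect that difference and are no evidence of a group change. With a mean of at least 5 FPKM 1460 genes were higher, among 9478 tested. With no filter on low values 22887 genes were tested, 2454 were higher and 1261 lower, and 2676 of the 3970 original calls remained. Lower genes numbered 2643 after quantile normalisation, 2615 after TPM-like rescaling and 1038 with the fold minimum. The median log2 fold change of all genes was −0.04 as deposited, −0.14 after quantile normalisation and −0.22 after TPM-like rescaling, so the scaling moves both counts. With the set number as a block, 2550 genes were higher and 2176 lower, 3940 original calls remained, and Tead4 kept −1.42 (adjusted p = 0.00360 in limma); Dppa5a (0.0115) and Krt18 (0.0284) gained a call. Libraries of a set deviated together only weakly (correlation 0.123 across genes, 2 pairs), so they are not treated as pairs. With an estimated correlation 0 lists passed, a test with only 2 residual degrees of freedom.

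Of 113 called genes named by the fixed rule or picked singly later, 62 kept call and direction in all alternatives run and 0 reversed. Hand1, a list member outside that number, lost its call with no filter on low values (0.0774) and without Tead4 shRNA library 1 (0.195) or 2 (0.182). Among named genes without a call in the original fit, Cdx2 was −0.023 and Yap1 −0.11 after TPM-like rescaling, with no call. With 1 library left out Cdx2 lay between −0.040 and 0.37 and Tead1 between −0.40 and 0.11, while Elf5 lay between −0.45 and 0.92 and Krt8 between −1.04 and 0.10, each with a call without scramble library 2 (adjusted p = 0.00288 and 0.00229). The labyrinth list turned downward with a pseudocount of 0.1 (camera adjusted p = 0.995), a mean of at least 5 FPKM (0.282), quantile normalisation (0.985) and the block (0.902), and had 0.731 to 0.983 with 1 library left out. Also with 1 library left out, direction changed for the stem cell list (0.0417 to 0.734), the spongiotrophoblast list (0.448 to 0.743), the oxidative phosphorylation list (0.0656 to 0.941) and, under quantile normalisation, the ribosomal list (0.681). The cause of these changes was not tested. Unknown fragment numbers limit what can be said of genes near 0.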

Other observations

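The genes described first in this part and the tests of each explanation were chosen after the result was seen, while the mitosis and stem cell lists and the processing alternatives used here were fixed before. Hox genes pattern the body axis, and most of their rows that passed the level filter were higher with Tead4 shRNA. Of 15 rows tested 12 rose, 1 fell and 2 had no call in limma. The 12 that rose had scramble means under 1 FPKM, so they passed the filter through their Tead4 shRNA values. With no filter on low values, 16 of 33 rows rose and 1 fell. The 20 fibroblast markers and the Y-linked genes were higher in the same libraries. No list test was run on this family; without Tead4 shRNA library 1, 9 of 14 rows rose and without library 2, 8 of 12, and none fell. Hoxb9 went from 0.364 to 14.8 FPKM, Hoxa5 from 0.154 to 12.1 FPKM and Hoxc6 from 0.369 to 12.5 FPKM, whereas Hoxc13 fell from 5.01 ± 0.225 to 1.33 ± 0.0690 FPKM (SD, n = 2), a call lost without Tead4 shRNA library 1 (limma adjusted p = 0.0841) or 2 (0.0936). Among single genes, picked after their values were seen and not tested as a group, the repressors Zeb1 (0.187 to 10.1 FPKM), Zeb2 (0.119 to 11.5 FPKM, in a row shared with Mir5129) and Snai2 (0.0987 to 8.14 FPKM) and N-cadherin, Cdh2 (0.123 to 4.08 FPKM), were higher. E-cadherin, Cdh1 (219 ± 4.12 to 130 ± 23.4 FPKM), the adhesion molecule Epcam (159 ± 28.9 to 72.3 ± 1.41 FPKM) and the keratin Krt7 (249 ± 66.4 to 89.8 ± 26.4 FPKM) were lower. The keratins Krt8 (log2 fold change −0.47) and Krt18 (−0.92) had no call with all libraries. Without scramble library 2 both passed as lower, Krt8 at −1.04 (limma adjusted p = 0.00229) and Krt18 at −1.30 (0.000759), and without library 1 Krt8 was at 0.10. Krt18 also passed after quantile normalisation (0.0252) and TPM-like rescaling (0.0409), in a range of 0.000759 to 0.456. Without a Tead4 shRNA library, Cdh1, Epcam and Krt7 reached limma adjusted p of 0.334, 0.146 and 0.164 at most, and Cdh1 had 0.0639 with no filter on low values.

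Further single genes picked in the same way rose from levels under 1 FPKM. The prostaglandin synthase Ptgs2 went from 0.164 to 201 FPKM, and the chemokines Ccl7 from 0.370 to 134 FPKM and Cxcl1 from 0.227 to 71.1 FPKM. The acute phase protein Saa3 went from 0.672 to 102 FPKM and the cytokine Tslp from 0.0905 to 78.6 FPKM. Ptprc, a marker of blood cells, was at most 0.0285 FPKM in any library.

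The first pattern weighed is the joint rise of fibroblast markers and Y-linked genes. A change of expression within cells that carry no Y chromosome cannot give Y-linked transcripts. The lowest Y-linked value in a Tead4 shRNA library, 2.29 FPKM (Kdm5d), argues against it for those 4 genes, though they were chosen after their values were seen. Whether the fibroblast markers also rose within such cells was not tested. Replacement of the whole culture by another Y-bearing line, of trophoblast or other type, is argued against by Xist. Its lowest Tead4 shRNA value was 0.530 of the scramble mean (antisense Tsix at 0.0802 FPKM or less, strand use unknown). RNA from Y-bearing cells of another type, for which feeder-like fibroblasts are a candidate source, stays open: 4 of the 4 Y-linked genes were at 1 FPKM or more in both Tead4 shRNA libraries and under 0.1 FPKM in both scramble libraries, and the fibroblast transcripts Thy1 (159 FPKM), Col1a2 (115 FPKM) and Acta2 (94.8 FPKM) were abundant, but these genes are the pattern itself and cannot test it. The labels name no feeder cells. The puromycin selection is meant to remove cells without the vector, but whether other cells were resistant or joined after selection is unknown. Of the 20 markers, 7 are also at 1 FPKM or more with scramble shRNA, and 0 stand in another list. Which Y-bearing cells may be mixed with cells that express Xist, with a Y-bearing trophoblast line as one possibility, stays open and untested.

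The second pattern is the fall of the mitosis genes. As the whole cause, dilution of trophoblast RNA by non-dividing cells would lower stem cell genes as much, provided those cells did not express them. The stem cell median lay 1.35 above that of the mitosis genes on the log2 scale, and 1.11 to 1.47 above it with 1 library left out. The SD between the stem cell genes was 0.78. This argues against dilution only by cells that lack these transcripts. What the other cells express is unknown, and Fgfr2 of this list stands in a row shared with Ctbp2. Scaling as the whole cause would move all genes alike, but the mitosis median lay 1.26 below that of all genes. The SD of 0.23 between the mitosis genes is a spread between genes, not an error of this gap. The gap was 1.23 after quantile normalisation and 1.29 after TPM-like rescaling. It was 0.95 to 1.61 over the alternatives, some of which, such as the block and no intensity trend, cannot move it. Some transcripts, singled out after their values were seen, fell about as much as the mitosis genes and go with dilution. They were Krt7 (−1.47), Epcam (−1.11), Igf2 (−1.46) and the row of Gata3 (−1.70), with Cdh1 (−0.77) and Xist (−0.75) lower by less. Of the 19 stem cell genes tested, 2 lay below the mitosis median, Sall4 (−1.92) and the row of Gata3. With all libraries Cdx2 (0.16) and Elf5 (0.23) were not lower. Krt8 (−0.47) and Krt18 (−0.92) had no call with all libraries, though Krt18 lay below Cdh1 and Xist. Krt18 passed as lower after quantile normalisation and TPM-like rescaling. Partial dilution, a compensating rise of stem cell genes, and an effect of Tead4 on division may each contribute and were not separated.

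The third pattern is the fall of Tead4 itself. It lay 1.48 below the stem cell median (difference −1.48), beyond the SD of 0.78, but without scramble library 1 the difference was −0.72, within it. Leaving out that library moved Tead4 from −1.42 to −1.13 and the stem cell median from 0.06 to −0.41. Knockdown and dilution by cells without Tead4 therefore cannot be told apart for this gene. The scramble libraries differ both for Tead4, at 45.3 and 29.8 FPKM, and for the stem cell genes it is set against.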
